A study of Mus musculus with 20 samples.

How the data were processed

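Gene expression had been measured on Affymetrix mouse gene arrays of whole-transcript design, 1 array for each of 20 gastrocnemius samples of adult male C57BL/6 mice, per the labels. RNA was isolated with a column kit, and 250 ng of total RNA was amplified and labelled with biotin for each array, per the labels' protocols. The groups were CON, NCoR1-MKO, WT and PGC-1alpha-mTg, with 5 arrays in each, taken from the sample names. The labels do not say outright that each array came from its own mouse, so p-values measure only the spread between these samples, which may in part be technical. The genotype of the CON mice is not given in the sources used here.

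The deposited values were log2 expression values made by RMA, which corrects the background, brings arrays to common quantiles and summarises the probes of a set, per the submitters' processing notes, which also name the Partek software and give no version of either. The log base was taken from the method named, and the values ranged from 2.66 to 14.47. No genome build or annotation is named in the sources used here, so no coordinates are given. The quantiles of the arrays differed by at most 0.0630 on average within a cohort (CON with NCoR1-MKO, WT with PGC-1alpha-mTg) and by 0.169 to 0.228 between the cohorts, so the cohorts appear to have been normalized separately. No array duplicated another: 0 pairs held identical values. An array has no sequencing depth. Its precision rests on the number of arrays, and a probe set's background was not given.

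Probe sets were named from the platform's gene table. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none here. Of those with 1 symbol, 21698 matched a gene in the RefSeq table of assembly GRCm38.p6 by Entrez number, and 0 symbols changed. Only probe sets with 1 symbol were tested. For the 999 genes with more than 1 probe set, the one with the highest mean over all 20 arrays was used, which left 19938 genes, and no dim gene was removed. Ncor1 was not among them and is not analysed here.

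The 4 group means were fitted per gene to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes). The contrasts were NCoR1-MKO against CON, PGC-1alpha-mTg against WT, the difference of these effects, and WT against CON. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with calls at an adjusted p under 0.05. Overlaps of calls were set beside the number for independent lists. Both comparisons have their own controls, so no control array was shared, but the fit used the same spread of a gene for both. For 33 gene lists, fixed before the data were examined, camera was run with an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. fry was an alternative. It asks whether the genes of a list move on balance one way, and compares the list with no other genes. Of 511 genes wanted by symbol, 472 were measured. Members were also adjusted over the list alone. The genes named in the text come from a rule that was also set before the data were examined, but not every gene it takes is named. It takes, per comparison, the targeted genes, the 10 largest rises and 10 largest falls among called genes with settled names, up to 4 called members per list (up to 2 with the smallest p where none is called), up to 10 shared genes per direction and up to 5 genes per direction for the difference. Genes named outside the rule are said to be so.

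The fit was tested on simulated data with the real spread. For NCoR1-MKO against CON, with 50 of 19938 genes changed at each size, 28 percent were recovered at a log2 change of 0.2, 98 percent at 0.5 and 100 percent at 1 and 2, with 10 false calls among 173. For PGC-1alpha-mTg against WT the shares were 26, 98, 100 and 100 percent, with 13 false calls among 175. Small changes were thus often missed in this setting. The real comparisons called more genes, 525 and 5575, which loosens the adjusted threshold. These shares therefore do not carry over to them, least of all to the transgenic mice. The simulation also gave each gene the same spread in all groups. In the list test 3 of 3 shifted lists were recovered, with 0 false calls among 30 others, but the simulated genes varied independently, so this does not give the rate of false calls for lists of correlated genes. Over other splits of the real arrays the same test called a median of 8 lists for the knockout, 14 for the transgenic mice and 11 for the difference.

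Alternatives set before the data were examined were quantile normalization across the 20 arrays, centring each array on its median, leaving out the dimmest 40 percent of genes, the mean of a gene's probe sets, all probe sets, only the 10 arrays of a comparison, eBayes with trend and robust, array weights, no moderation, the replicate number as a block, a fold minimum of 1.2, the other set tests and leaving out each array in turn. Chosen after the data were seen were leaving out CON 1 with NCoR1-MKO 5 or PGC-1alpha-mTg 2 with 3, and covariates for the olfactory receptor, slow-fibre or glucocorticoid-response signal of an array. Whether other splits of the arrays give results as large was counted over 100 splits per test, the real one included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.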

Results

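Gene expression was measured in the gastrocnemius, a calf muscle of mixed but mostly fast fibres, of adult male C57BL/6 mice. The 20 Affymetrix mouse gene arrays fell into 4 groups of 5. CON were the controls of NCoR1-MKO, mice without the nuclear receptor corepressor NCoR1 in muscle. WT were the controls of PGC-1alpha-mTg, mice that overexpress the transcriptional coactivator PGC-1alpha in muscle. The values were RMA expression values on the log2 scale for 35556 probe sets, from which 19938 genes were tested. Array medians lay between 6.03 and 6.08 in the 10 arrays of CON and NCoR1-MKO, and between 5.84 and 5.91 in the 10 arrays of WT and PGC-1alpha-mTg. Within a group, arrays correlated with each other at r from 0.996 to 0.998 in the first cohort and from 0.992 to 0.998 in the second. The median SD of a gene was 0.0856 in CON, 0.0872 in NCoR1-MKO, 0.0775 in WT and 0.105 in PGC-1alpha-mTg. The number of arrays, 5 per group, limits the precision. All changes below are log2 fold changes ± SE against the cohort's own controls, with n = 5 per group. The words rose and fell are kept for changes with a limma adjusted p under 0.05.

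The targeted genes were examined first. Ncor1 was not analysed here, because no probe set used here carried its name, so the NCoR1-MKO label was not checked against the values. Ppargc1a, which encodes PGC-1alpha, rose by 1.83 ± 0.07 in PGC-1alpha-mTg (adjusted p = 9.88e-15), a 3.55-fold increase. Its probe set 10529979 read 9.59 ± 0.14 (SD, n = 5) in WT and 11.42 ± 0.08 in PGC-1alpha-mTg. The 5 transgenic arrays ranged from 11.36 to 11.53 and the WT arrays from 9.38 to 9.75, so no WT array reached the level of a transgenic one. The dimmer Ppargc1a probe set, 10529977, moved the other way. It was 8.08 ± 0.13 (SD, n = 5) in WT and 7.08 ± 0.23 in PGC-1alpha-mTg, and fell by 1.00 ± 0.11 (adjusted p = 1.55e-06 among all probe sets). In the knockout Ppargc1a changed by -0.10 ± 0.07 (adjusted p = 0.634), which did not pass the test, with 10.49 ± 0.13 in CON and 10.39 ± 0.07 in NCoR1-MKO.

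**Figure D1:**
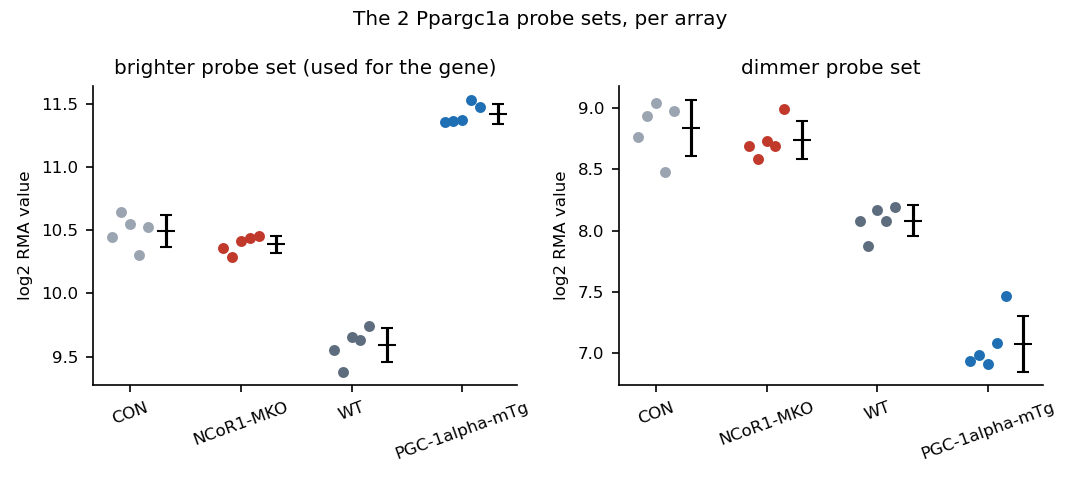
Log2 RMA values of the 2 Ppargc1a probe sets on each array, by group (points, 5 arrays per group), with the group mean ± SD beside them. The brighter probe set reads 11.36 to 11.53 in PGC-1alpha-mTg against 9.38 to 9.75 in WT, whereas the dimmer one reads 6.92 to 7.47 against 7.87 to 8.19.

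The comparison of NCoR1-MKO with CON asks which muscle transcripts depend on the corepressor. Muscle without NCoR1 carried slightly more transcript for the machinery of oxidative metabolism, and much less of a small number of single genes. Of 84 respiratory chain genes, 21 rose and none fell. The median change was 0.13, or 1.09-fold, and 81 of the 84 values were positive. The largest falls were those of Htra4, a serine protease of the HtrA family, at -2.76 ± 0.10 (probe set 10577782), and of Mss51, a mitochondrial protein enriched in fast fibres, at -2.27 ± 0.15 (probe set 10417887). The largest rise was that of Scd2, a desaturase that makes monounsaturated fatty acids, at 1.18 ± 0.11 (probe set 10463355). In all, 525 genes were called, 261 higher and 264 lower. Only Scd2 and Pcbd1 rose 2-fold or more, and 10 genes fell that far. The split by direction depended on the scaling. With each array centred on its median 177 of 432 called genes were higher, and after quantile normalization across the 20 arrays 319 of 611.

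Among the other strong rises were Pcbd1, which takes part in recycling tetrahydrobiopterin, at 1.12 ± 0.11, and the cytokine gene Il15 at 0.98 ± 0.10. Cacna2d4, an auxiliary subunit of voltage-gated calcium channels, rose by 0.97 ± 0.12. The lipid droplet protein gene Plin3 rose by 0.87 ± 0.11, the nicotinamide riboside kinase gene Nmrk2 by 0.80 ± 0.16 and the cardiac actin gene Actc1 by 0.69 ± 0.15. The other strong falls were those of the mitochondrial carrier gene Slc25a30 (-1.32 ± 0.22), the secreted glycoprotein gene Lgi1 (-1.52 ± 0.21) and Odf3l2 (-1.48 ± 0.30). Ostn, which encodes the muscle-derived peptide musclin, fell by 1.32 ± 0.12, and the amylase gene Amy1 fell by 1.30 ± 0.10. Npnt, an extracellular matrix ligand of integrins, changed by -1.27 ± 0.15, Pld5 by -1.15 ± 0.09 and the T cell costimulatory receptor gene Cd28 by -1.13 ± 0.07. Musk, the receptor kinase that organises the neuromuscular junction, fell (-0.91 ± 0.09 (adjusted p = 1.65e-06)), as did Mstn, which encodes myostatin, an inhibitor of muscle growth (-0.63 ± 0.08 (adjusted p = 6.54e-05)). Each of the genes named so far in this comparison kept its call whichever array was left out. The clock repressor gene Nr1d1 (0.98 ± 0.23), the immediate early gene Egr1 (0.74 ± 0.19) and Trp53i11 (0.80 ± 0.21) were also called, with less certainty. Nr1d1 missed the threshold without any 1 of CON 1, 2 or 3 or NCoR1-MKO 1 or 2, where its change lay from 0.85 upwards and its adjusted p reached 0.0717. Egr1 missed it without CON 2, 3 or 5 or NCoR1-MKO 1, 2 or 3 (adjusted p up to 0.102). Trp53i11 missed it without CON 2, 3, 4 or 5 or NCoR1-MKO 1, 2 or 3 (adjusted p up to 0.115).

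Of 33 gene lists fixed beforehand, 15 passed the set test (camera with a preset correlation), and the oxidative ones stood out. Complex I had 7 of 35 measured members higher, and 26 when adjusted over the list alone, with a median change of 0.14 (adjusted p = 8.36e-24; adjusted p = 0.00330 with an estimated correlation). Ndufb5 (0.30 ± 0.04), Ndufb8 (0.23 ± 0.04) and Ndufv1 (0.20 ± 0.04) were among them. Complexes II and III with cytochrome c had 5 of 14 members higher, Uqcrq among them at 0.18 ± 0.04, and 12 when adjusted over the list alone (adjusted p = 0.00888 with an estimated correlation). The largest rise of that list, Uqcrfs1 (0.25), missed the threshold without CON 5 or NCoR1-MKO 3 (limma adjusted p up to 0.0647). ATP synthase had 7 of 16 higher, and 11 when adjusted over the list alone (adjusted p = 0.00398 with an estimated correlation). Complex IV had 2 of 19, and 7 when adjusted over the list alone (adjusted p = 0.0486 with an estimated correlation). In the TCA cycle, which feeds the chain, 7 of 17 genes rose, and 13 when adjusted over the list alone (adjusted p = 0.0197 with an estimated correlation). They included Sucla2 (0.28 ± 0.04), the fumarate hydratase gene Fh1 (0.21 ± 0.04) and Dlat of the pyruvate dehydrogenase complex (0.20 ± 0.04). These 5 lists kept their calls with an estimated correlation. The counts of single members depended on the arrays: without CON 3, CON 5 or NCoR1-MKO 3 the respiratory chain genes called higher numbered 10, 12 and 11. Without CON 2, 3, 4 or 5 or NCoR1-MKO 1, 3, 4 or 5 the ATP synthase genes numbered 1 to 4. Without CON 3 or NCoR1-MKO 3 or 5 the TCA cycle genes numbered 4. Over the fits that left out 1 array the called members numbered 2 to 6 for complexes II and III and 0 to 3 for complex IV, with the lowest counts without CON 3.

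Fatty acid uptake and oxidation had 8 of 23 genes higher, 14 when adjusted over the list alone, at a median of 0.18. Its set test passed (adjusted p = 1.37e-14) but not with an estimated correlation (adjusted p = 0.132 with an estimated correlation). The rises included Acadvl, the very long chain acyl-CoA dehydrogenase (0.34 ± 0.05), Etfdh, which passes electrons on to ubiquinone (0.30 ± 0.06), and the acylcarnitine carrier Slc25a20 (0.30 ± 0.06). Without CON 3 or NCoR1-MKO 3 only 4 genes of this list were called, and without CON 4 or 5 or NCoR1-MKO 1 or 5 only 5. Branched-chain amino acid catabolism had 2 genes higher and 1 lower of 18, 7 and 1 when adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). With 1 array left out, 0 to 4 were called higher and 0 to 1 lower. Bckdha, which rose by 0.17, missed the threshold in 17 of 20 such fits. Ketone and lactate handling, a list that also holds the aminotransferase genes Kyat1, Kyat3, Aadat, Got1 and Got2, had 2 of 11 higher. They were the D-lactate dehydrogenase gene Ldhd (0.30 ± 0.04) and the aminotransferase gene Got1 (0.24 ± 0.04). When adjusted over the list alone 4 were higher and 1 lower (adjusted p = 0.141 with an estimated correlation). The mitochondrial ribosome list had 2 of 77 members higher, also when adjusted over the list alone (adjusted p = 0.193 with an estimated correlation). Mitochondrial dynamics and import had 1 of 19, and 4 when adjusted over the list alone (adjusted p = 0.220 with an estimated correlation; 0.0550 without CON 4 at the preset correlation). Antioxidant defence had none of 13 called, and 2 when adjusted over the list alone (adjusted p = 0.180 with an estimated correlation). That last list missed the threshold in 5 of the fits that left out 1 array, at adjusted p up to 0.227. Over all fits that left out 1 array the called members ranged from 0 to 3 for the mitochondrial ribosome and from 0 to 2 for mitochondrial dynamics.

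Slow-fibre genes were lower in the knockout. Their list also holds Myh2, the myosin of fast IIa fibres, called in neither model (-0.05 in the knockout, -0.15 in the transgenic mice). Of 14 members, 2 fell over all genes and 7 when adjusted over the list alone, at a median of -0.43 (adjusted p = 5.53e-06; adjusted p = 0.180 with an estimated correlation). The slow myosin light chain genes Myl2 (-0.91 ± 0.18 (adjusted p = 0.00445)) and Myl3 (-0.66 ± 0.16 (adjusted p = 0.0229)) were the called members, and the slow myosin heavy chain Myh7 stood at -0.98 ± 0.30 (adjusted p = 0.0877). Myl3 missed the threshold without CON 1 or 2 or NCoR1-MKO 5 (adjusted p up to 0.0766), and 1 to 5 members of the list were called with 1 array left out. Of the lipogenesis and LXR target list, 3 of 18 genes rose and 1 fell, 6 and 1 when adjusted over the list alone (adjusted p = 0.00141; adjusted p = 0.228 with an estimated correlation; 0.0656 without NCoR1-MKO 5 at the preset correlation). Beside Scd2 these were the cholesterol exporter gene Abca1 (0.55 ± 0.09) and the lipogenic transcription factor gene Srebf1 (0.43 ± 0.11 (adjusted p = 0.0287)), while the malic enzyme gene Me1 fell (-0.27 ± 0.05). Srebf1 missed the threshold without CON 1, 2 or 5 or NCoR1-MKO 1, 2 or 4 (adjusted p up to 0.0912). The mean of the list was 0.24 above the CON mean on CON 1 and 0.38 above it on NCoR1-MKO 5, the arrays whose adipocyte marker means were highest in their groups, 0.41 and 0.42 above CON. Insulin and growth signalling was lower as a list, with 1 of 17 called and 2 when adjusted over the list alone (adjusted p = 0.00615; adjusted p = 0.0561 with an estimated correlation). Endothelial markers were higher, with 1 of 12 called, 5 when adjusted over the list alone and a median of 0.20 (adjusted p = 3.02e-06; adjusted p = 0.141 with an estimated correlation). With 1 array left out, 0 to 2 members were called in either of these lists. The mitochondrial gene regulators did not pass as a list (adjusted p = 0.0526), but did after quantile normalization across the 20 arrays (adjusted p = 0.0336), and Ppargc1b, a relative of Ppargc1a, and the mitochondrial transcription factor gene Tfam rose (0.51 ± 0.12 and 0.25 ± 0.06). Ppargc1b missed the threshold without CON 3 or NCoR1-MKO 3 or 4, and Tfam without CON 3, 4 or 5 or NCoR1-MKO 2 or 5 (adjusted p up to 0.0642 and 0.0782). PPAR target genes (adjusted p = 0.0513; 0.0398 with each array centred on its median) and the NCoR complex and nuclear receptors (adjusted p = 0.397) did not pass, nor did markers of smooth muscle (adjusted p = 0.489), macrophages (adjusted p = 0.629), adipocytes (adjusted p = 0.455), fibroblasts (adjusted p = 0.395), nerve (adjusted p = 0.489) or blood (adjusted p = 0.670).

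The comparison of PGC-1alpha-mTg with WT asks what the coactivator does when overproduced. Muscle with extra PGC-1alpha carried more transcript for nearly the whole oxidative machinery of the mitochondrion. Of 84 respiratory chain genes, 82 rose and none fell, with a median of 0.52, or 1.44-fold. The largest rises were those of Tm6sf1, a membrane protein gene, at 2.26 ± 0.12, and of Kcng4, a modulatory potassium channel subunit, at 1.96 ± 0.08. The largest falls were those of Mss51 (-3.36 ± 0.15), of Neto2, an auxiliary protein of kainate receptors (-3.21 ± 0.21), and of Htra4 (-3.06 ± 0.10). In all, 5575 genes were called, 2371 higher and 3204 lower. Of these, 50 rose and 46 fell 2-fold or more.

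Beyond these, the carbonic anhydrase gene Car2 rose by 1.86 ± 0.12, the peptide transporter family member Slc15a5 by 1.71 ± 0.21 and the phosphodiesterase family gene Gdpd1 by 1.69 ± 0.05. Sh2d4a rose by 1.64 ± 0.07, the CDP-diacylglycerol synthase gene Cds1 by 1.63 ± 0.07 and adipogenin, Adig, by 1.61 ± 0.09. Prkag3, the regulatory subunit of AMP-activated kinase typical of fast glycolytic muscle, fell (-1.82 ± 0.08), as did Ostn (-1.75 ± 0.12), Bex1 (-1.72 ± 0.14), Actc1 (-1.65 ± 0.15), Ociad2 (-1.53 ± 0.06) and Tmem100 (-1.50 ± 0.11).

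Oxidative lists rose together. Complex I had 34 of 35 members higher, at a median of 0.57, and all of them when adjusted over the list alone (adjusted p = 0.000202 with an estimated correlation). Ndufb10 (0.93 ± 0.05) and Ndufa5 (0.88 ± 0.04) led. All 14 members of complexes II and III with cytochrome c rose, led by Uqcrfs1 (0.83 ± 0.06) (adjusted p = 0.00107 with an estimated correlation). So did all 16 of ATP synthase (adjusted p = 0.000404 with an estimated correlation), and 18 of 19 genes of complex IV, led by Cox4i1 (0.94 ± 0.04) (adjusted p = 0.000959 with an estimated correlation). For these 3 lists the counts adjusted over the list alone were the same. The TCA cycle list had 16 of 17 genes higher, also when adjusted over the list alone, at a median of 0.59 (adjusted p = 0.00264 with an estimated correlation). Dlat (1.01 ± 0.04) and Dlst (0.88 ± 0.04), core enzymes of the pyruvate and oxoglutarate dehydrogenase complexes, led it. Fatty acid uptake and oxidation had 22 of 23 higher, 23 when adjusted over the list alone, at a median of 0.66 (adjusted p = 0.0152 with an estimated correlation). Acadvl (1.19 ± 0.05), Acadl (0.98 ± 0.07) and Slc25a20 (0.93 ± 0.06) rose most. PPAR target genes had 8 of 12 higher and 1 lower, 9 and 1 when adjusted over the list alone (adjusted p = 0.0417 with an estimated correlation). The uncoupling protein gene Ucp3 (0.95 ± 0.16) and the lipid droplet gene Plin5 (0.78 ± 0.08) rose. The nuclear receptor genes Esrrb (1.35 ± 0.08) and Esrra (0.66 ± 0.05), partners of PGC-1alpha, rose with Tfam (0.55 ± 0.06). The regulators as a list had 6 of 17 higher, to which 1 lower was added when adjusted over the list alone, and did not pass (adjusted p = 0.0717). They passed after quantile normalization across the 20 arrays (adjusted p = 0.0207, 7 higher and 1 lower) and without PGC-1alpha-mTg 2 and 3 (adjusted p = 0.0142). In the values as deposited their median change was -0.003 and their mean 0.16, and 9 of the 17 changes were negative.

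The mitochondrial ribosome rose in 62 of 77 members, 65 higher and 1 lower when adjusted over the list alone (adjusted p = 0.00607 with an estimated correlation), led by Mrpl45 (0.87 ± 0.05). The cytosolic ribosome went the other way, with 27 of 58 members lower and 1 higher, 28 and 1 when adjusted over the list alone, at a median of -0.13 (adjusted p = 3.61e-07; adjusted p = 0.0582 with an estimated correlation). Rpl36a fell by 0.38 ± 0.07 and Rpl10 fell by 0.32 ± 0.04. The member that rose, Rpl3l (0.18 ± 0.04), is a form specific to striated muscle and was named after its value was seen. Mitochondrial dynamics and import had 15 of 19 higher, 16 when adjusted over the list alone, among them the fusion gene Mfn1 (0.68 ± 0.04) (adjusted p = 0.00344 with an estimated correlation). Branched-chain amino acid catabolism had 15 of 18 higher and 1 lower, 16 and 1 when adjusted over the list alone, Hibch leading (0.79 ± 0.06) (adjusted p = 0.0321 with an estimated correlation). Ketone and lactate handling, with its aminotransferase genes, had 8 of 11 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.0149 with an estimated correlation). The monocarboxylate importer gene Slc16a1 rose (1.05 ± 0.10), while Slc16a3, the lactate exporter of glycolytic fibres, fell (-0.47 ± 0.06), a member named after its value was seen. Antioxidant genes split, 5 higher and 2 lower of 13, 6 and 2 when adjusted over the list alone (adjusted p = 0.0358; adjusted p = 0.144 with an estimated correlation; 0.0587 without PGC-1alpha-mTg 4 at the preset correlation). The mitochondrial superoxide dismutase Sod2 (0.67 ± 0.04) and Prdx2 (0.72 ± 0.08) rose, and Nqo1 fell (-0.48 ± 0.09).

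Genes of contraction and of glycogen use mostly had negative changes, though fewer of them were called. Values were negative for 14 of 15 fast-fibre, 12 of 14 slow-fibre and 18 of 21 glycolysis and glycogen genes. Of 15 fast-fibre genes, 9 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0178 with an estimated correlation). The sarcomeric genes Actn3 (-0.28 ± 0.04) and Myoz3 (-0.90 ± 0.05) fell, and Myh1, the myosin of fast IIx fibres, rose (0.32 ± 0.05). Of 14 slow-fibre genes, 7 fell and 2 rose, also when adjusted over the list alone, at a median of -0.61 (adjusted p = 0.0198; adjusted p = 0.3999 with an estimated correlation). Myl2 (-0.81 ± 0.18) and the slow troponin gene Tnnt1 (-0.72 ± 0.21) fell. Myh7 fell too (-0.96 ± 0.30), but not without WT 1 (-0.86) or PGC-1alpha-mTg 4 (-0.76). The members that rose were the oxygen store myoglobin, Mb (0.29 ± 0.05), and Casq2 (0.52 ± 0.11), both named after their values were seen. Glycolysis and glycogen genes had 8 lower and 2 higher of 21, 11 and 2 when adjusted over the list alone (adjusted p = 0.000178; adjusted p = 0.0874 with an estimated correlation). The phosphorylase kinase genes Phkb (-0.91 ± 0.05) and Phka1 (-0.45 ± 0.05) fell, whereas the glycogen branching enzyme gene Gbe1 rose (0.50 ± 0.07). Myogenic regulators and satellite cell genes had 8 of 13 lower, also when adjusted over the list alone (adjusted p = 0.00264 with an estimated correlation), among them Myf6 (-0.77 ± 0.09) and Myod1 (-0.53 ± 0.13). Clock genes had 5 of 16 lower, also when adjusted over the list alone (adjusted p = 0.0149 with an estimated correlation), Dbp among them (-0.40 ± 0.07). Srebf1 (-1.30 ± 0.11) and Scd2 (-0.96 ± 0.11) fell, while their list split into 3 higher and 5 lower of 18, 4 and 5 when adjusted over the list alone, with a median of 0.13 and a mean of -0.07, and did not pass (adjusted p = 0.621).

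Vessel-related genes moved as well. Endothelial markers had 10 of 12 higher, also when adjusted over the list alone, at a median of 0.39 (adjusted p = 2.71e-06; adjusted p = 0.0874 with an estimated correlation), with Kdr, a VEGF receptor, at 0.58 ± 0.15. Among angiogenic factors 5 rose and 1 fell of 11, 6 and 2 when adjusted over the list alone, Vegfb among the rises (0.99 ± 0.04) (adjusted p = 0.0243; adjusted p = 0.205 with an estimated correlation; 0.0584 without PGC-1alpha-mTg 5 at the preset correlation). Smooth muscle and pericyte markers had 3 of 8 higher, also when adjusted over the list alone (adjusted p = 0.0358; adjusted p = 0.266 with an estimated correlation; up to 0.0896 without WT 2, WT 5 or PGC-1alpha-mTg 5 at the preset correlation). Fibroblast and matrix markers were lower, with 2 of 13 called and 1 when adjusted over the list alone (adjusted p = 0.0358; adjusted p = 0.419 with an estimated correlation). That call was lost without WT 1, 3 or 4 (adjusted p up to 0.0715), after quantile normalization across the 20 arrays (0.0578) and without PGC-1alpha-mTg 2 and 3 (0.0878). Macrophage markers (4 of 16 higher, adjusted p = 0.0625), adipocyte markers (2 of 9 higher, adjusted p = 0.248), nerve markers (2 of 8 lower, adjusted p = 0.254) and blood markers (adjusted p = 0.692) did not pass, with the same counts when adjusted over the list alone. Only 2 macrophage markers were called without WT 5, whereas the list passed without PGC-1alpha-mTg 2 and 3 (adjusted p = 0.00399) and without CON 1 and NCoR1-MKO 5 (adjusted p = 0.0294). With 1 array left out, 1 to 4 fibroblast and 1 to 2 nerve markers were called lower. Neuromuscular junction genes (2 higher and 5 lower of 17, adjusted p = 0.0775) also did not, although Musk fell by 1.31 ± 0.09. Nor did atrophy and denervation genes (adjusted p = 0.178), insulin and growth signalling (adjusted p = 0.115), the NCoR complex and nuclear receptors (adjusted p = 0.0689) or immediate early genes (adjusted p = 0.815). In the knockout the lists of the cytosolic ribosome, fast fibres, glycolysis, the neuromuscular junction, atrophy, myogenic regulators, angiogenic factors, immediate early genes and the clock did not pass, with adjusted p from 0.186 to 0.989. The 1027 olfactory receptor genes, taken as a measure of background signal, averaged 4.05 ± 0.02 (SD, n = 5) in WT and 4.11 ± 0.03 in PGC-1alpha-mTg, with the highest means on PGC-1alpha-mTg 2 and 3 (4.14 and 4.15). Without these 2 arrays 4304 genes were called, and without PGC-1alpha-mTg 3 alone 4868. Fewer arrays also mean less power, and no other pair of this group was left out, so the cause of the drop was not tested.

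**Figure D2:**
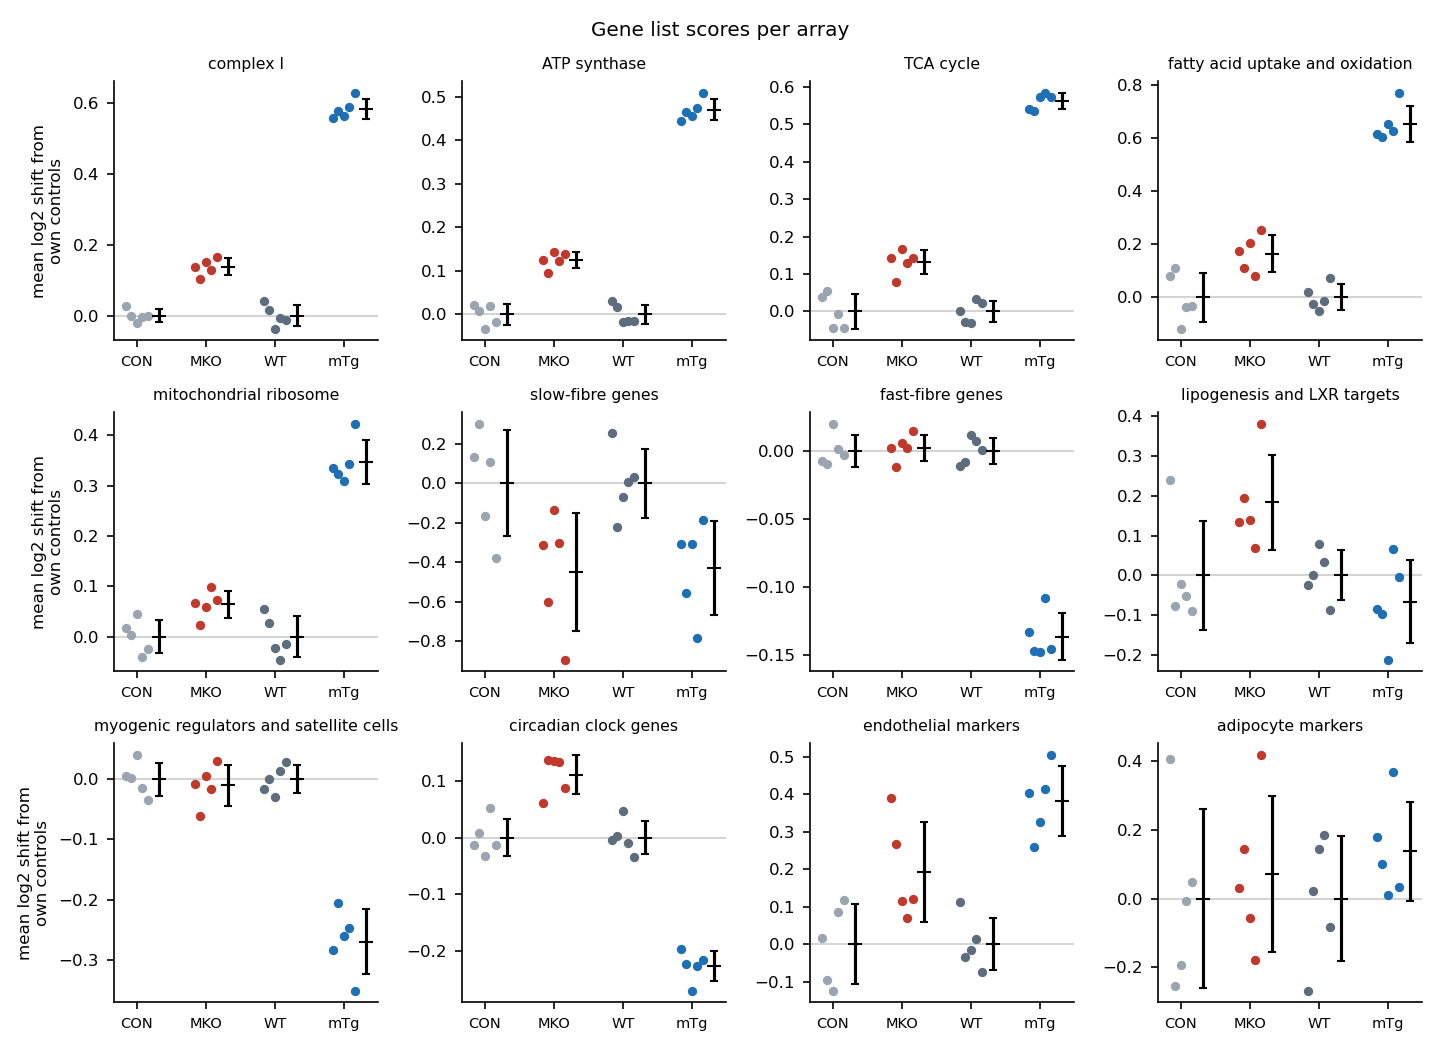
Mean log2 shift of 12 gene lists from their own controls on each array (points), by group, with the group mean ± SD beside them. Oxidative lists sit well above 0 on every PGC-1alpha-mTg array and slightly above 0 in NCoR1-MKO, and slow-fibre scores average -0.45 and -0.43.

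A change in both models was then sought, since the corepressor and the coactivator act on an overlapping set of nuclear receptors. Of the 525 genes called in the knockout and the 5575 called in the transgenic mice, 329 moved the same way in both, against 73.5 for independent lists. The comparisons share no control array, but the fit used the same spread of a gene for both, so the lists are not fully independent. With only the 10 arrays of each comparison, 377 knockout and 4973 transgenic genes were called, and 231 moved the same way in both. No number for independent lists is given for that fit. Of the 329 genes, 153 were higher in both (31.0 for independent lists) and 176 lower in both (42.4). In opposite directions went 61 genes, against 73.3. Il15 rose in both, by 0.98 ± 0.10 in the knockout and 1.09 ± 0.10 in the transgenic mice, as did Plbd1 (0.53 ± 0.08 and 1.49 ± 0.08), Mfsd4a (0.45 ± 0.05 and 1.44 ± 0.05) and the peroxisome gene Pex11a (0.41 ± 0.07 and 0.70 ± 0.07). Htra4, Mss51, Ostn, Musk and Pld5 fell in both, and so did Npnt (-0.95 ± 0.15 in the transgenic mice), Lgi1 (-0.89 ± 0.21), Slc25a30 (-0.89 ± 0.22) and Ctnna3, a catenin of cell junctions (-0.89 ± 0.09 and -1.03 ± 0.09). Of the 329 shared genes, 251 changed more in the transgenic mice, and 146 also differed between the effects. The median ratio of the transgenic to the knockout change was 1.53 over these 329 genes. Across all 19938 genes, which are not independent replicates, the fold changes correlated at Pearson r = 0.32 (Spearman 0.20). Without CON 3 the shared genes numbered 219 and the knockout genes 370.

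**Figure D3:**
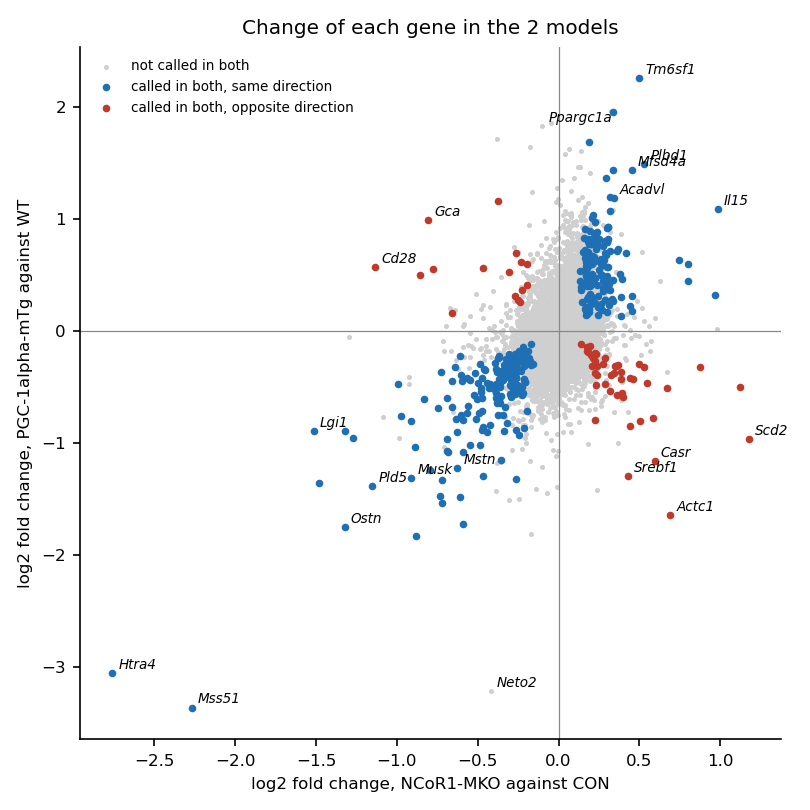
Log2 fold change of each of 19938 genes in NCoR1-MKO against CON (x axis) and in PGC-1alpha-mTg against WT (y axis), with the 329 genes called in the same direction and the 61 called in opposite directions coloured. Htra4 and Mss51 lie at the lower left, Il15 and Plbd1 at the upper right, and Scd2 and Actc1 to the right and below 0.

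**Figure D4:**
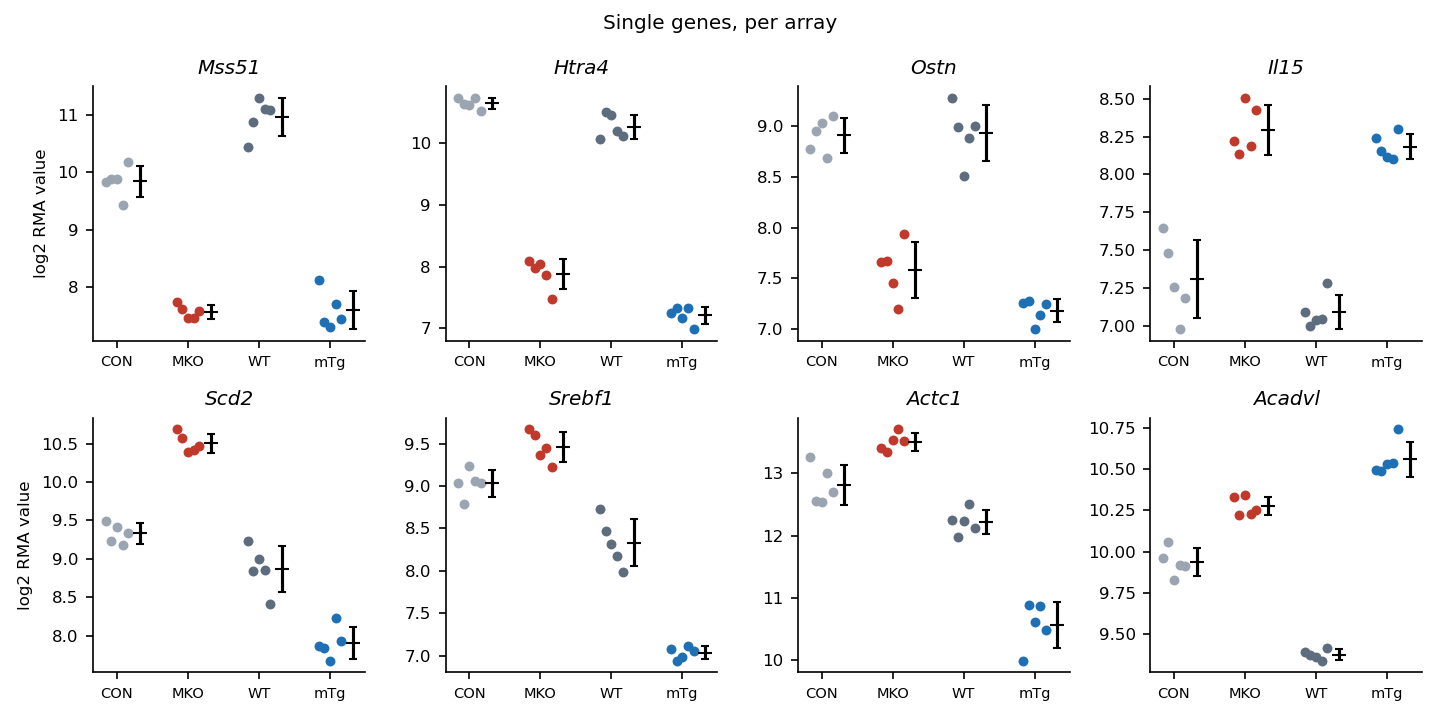
Log2 RMA values of 8 genes on each array, by group (points, 5 arrays per group), with the group mean ± SD beside them. Mss51, Htra4 and Ostn are lower and Il15 and Acadvl higher in both models, whereas Scd2 and Actc1 are higher in NCoR1-MKO and lower in PGC-1alpha-mTg.

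The difference between the 2 effects, the knockout effect minus the transgenic effect, was tested in the same fit and called 3022 genes. The oxidative program was the main contrast, with 75 of 84 respiratory chain genes changed less by the knockout, at a median difference of -0.40. Single lipogenic genes moved apart: Scd2 differed by 2.14 ± 0.16 and Srebf1 by 1.73 ± 0.15, both higher in the knockout and lower in the transgenic mice, while their list had 5 of 18 genes higher and 1 lower and adjusted p = 0.0444 (adjusted p = 0.398 with an estimated correlation). Actc1 differed by 2.34 ± 0.21 in the same way, while Neto2 (2.79 ± 0.30) and the calcium-sensing receptor gene Casr (1.75 ± 0.16) fell mainly with the transgene. On the other side stood Slc15a5 (-2.10 ± 0.30), Ppargc1a (-1.93 ± 0.09), Car2 (-1.91 ± 0.17), Sh2d4a (-1.82 ± 0.10) and the calcium-binding protein grancalcin, Gca (-1.80 ± 0.15). Of the 33 lists, 19 passed, 12 with a lower and 7 with a higher knockout effect. The lower ones included complex I (33 of 35 members; adjusted p = 0.000425 with an estimated correlation), fatty acid uptake and oxidation (22 of 23; adjusted p = 0.0249 with an estimated correlation) and the mitochondrial ribosome (50 of 77; adjusted p = 0.0122 with an estimated correlation). The higher ones included myogenic regulators (5 of 13; adjusted p = 0.00344 with an estimated correlation) and clock genes (5 of 16; adjusted p = 0.00861 with an estimated correlation). When adjusted over the list alone these 5 counts were 33, 22, 56, 7 and 6. With 1 array left out, 3 to 7 clock genes were called. Slow-fibre genes did not differ by the test (adjusted p = 0.980; median difference 0.01).

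**Figure D5:**
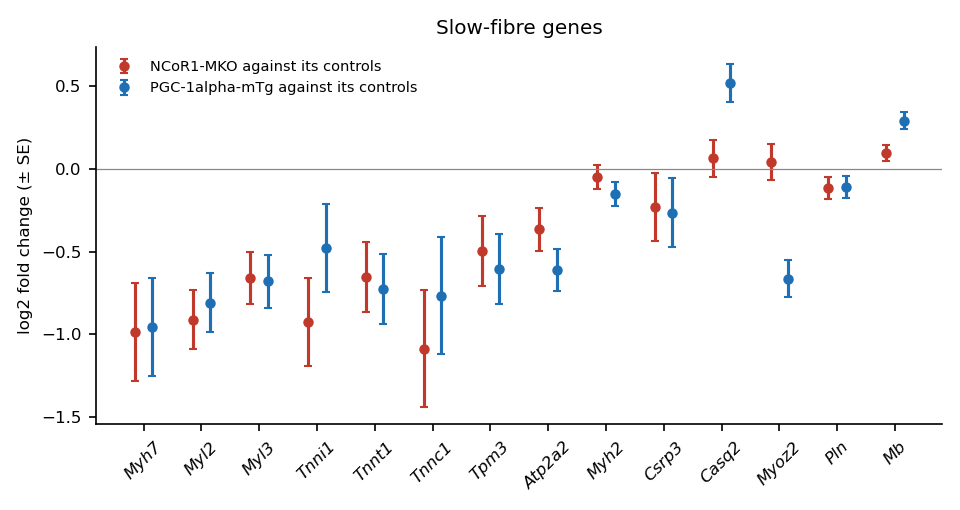
Log2 fold change ± SE of the 14 slow-fibre genes in NCoR1-MKO (red) and PGC-1alpha-mTg (blue), each against its own controls. Myh7, Myl2 and Myl3 lie well below 0 in both models, and Mb and Casq2 lie above 0 in PGC-1alpha-mTg.

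The control groups, WT against CON, set the background between the cohorts. This comparison called 12792 genes, 2248 higher and 10544 lower in WT, with a median change of -0.17 over all genes. After quantile normalization across the 20 arrays the split was 6265 higher and 5274 lower (median 0.02), and after centring each array on its median 5990 higher and 5985 lower (median 0.01). Each control group lies in its own cohort, and the cohorts appear to have been normalized separately, so a difference between the mouse lines, batch and normalization cannot be told apart here and no gene is named.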

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

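Of the tests in this part, the exact tests of the slow-fibre scores, the covariate fits, the ratio of fold sizes, the splits with an equal number of genes, and the rules that a covariate must move folds by 1 SE to count and that calls lost at unchanged fold size decide nothing were chosen only after the results were seen.

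Slow-fibre genes were lower in both models, at medians of -0.43 in the knockout and -0.61 in the transgenic mice. Random differences between pieces of muscle in their share of slow-fibre tissue remain a possible explanation, since the mean of the 14 genes gave an exact two-sided permutation p of 0.0556 in the knockout and 0.0159 in the transgenic mice. The mean of 6 contractile members, used below as a covariate, gave exact permutation p of 0.0317 and 0.00794. These members were chosen after the data were seen, so their p-values do not decide the question. A change in 1 shared share of slow-fibre tissue also stays open: across the 14 genes, which are not independent, the changes followed each gene's slope within groups at r = 0.926 in the knockout and r = 0.712 in the transgenic mice. A slow-fibre share altered by the genotype itself is the biological explanation and was not tested apart from uneven sampling.

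The Ppargc1a probe sets moved apart in PGC-1alpha-mTg. The dimmer one, which the main fit of genes did not use, fell by 1.00 on the log2 scale while the brighter one rose. That it does not read Ppargc1a is argued against by the 15 arrays without the transgene. There the deviations of both from their group means correlated at Pearson r = 0.829 (permutation p = 0.00019, adjusted p = 0.00038) and Spearman 0.814 (permutation p = 0.00039, adjusted p = 0.00039). The adjustment was over these 2 measures of the same relation. Pearson r was 0.664 without the 2 arrays farthest from the median and 0.838 (permutation p = 0.00295) in the 10 arrays of the knockout cohort. In the transgenic arrays it was 0.605. Other pairs of probe sets were not compared, so whether so close a relation is particular to this pair is not known. A shift of all probe sets of that brightness is argued against as well, since 0.381 percent of 1836 such probe sets fell as far and the median change was -0.07. A candidate explanation is that the dimmer probe set reads a part of the transcript that the transgene lacks, so that its fall is that of the resident gene; probe positions were not tested.

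Of the 329 genes that changed the same way in both models, 287 kept their calls in both with the olfactory receptor signal as a covariate. That covariate left the knockout folds in place (at most 0.0482 SE) but moved 10295 genes by over 1 SE in the transgenic mice. The shared folds stayed there at a median ratio of 0.996 (quartiles 0.884 and 1.06, lowest 0.169). This argues against a background shift as the whole source for the shared genes as a set. Over all genes the covariate cost 2148 of the 5575 transgenic calls and added 413, for reasons not tested. Among the shared genes the transgenic standard errors grew by a median factor of 1.29. With a glucocorticoid-response score 311 kept their calls, but it moved no fold by 1 SE (at most 0.762 SE in the knockout and 0.00155 SE in the transgenic mice), so this test, which the count alone would read against a stress state, decides nothing and that state stays open. With a slow-fibre score 164 kept their calls, just under the bound of 164.5, and the count alone would read for that tissue as the source, but standard errors grew by factors of 1.29 and 1.22 while the folds stayed at median ratios of 1.06 in the knockout and 1.03 in the transgenic mice. Uneven slow-fibre tissue as the source of the fold sizes is thus argued against for the shared genes as a set, not gene by gene. The lowest ratios were 0.179 in the knockout and 0.326 in the transgenic mice, and Odf3l2 lost its knockout call (limma adjusted p = 0.0833). Of 288 single-gene results, 42 lost the call with this score and 2 reversed. A shared action of the corepressor loss and the coactivator gain remains a hypothesis.

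The effects of the models differed by a direct test for 3022 genes. Of the genes, Neto2 (2.79), Actc1 (2.34), Scd2 (2.14), Casr (1.75) and Srebf1 (1.73) had the higher knockout effect. Slc15a5 (-2.10), Ppargc1a by its brighter probe set (-1.93), Car2 (-1.91), Sh2d4a (-1.82) and Gca (-1.80) had the higher transgenic effect. Of the lists, the median difference was -0.45 for complex I, -0.44 for complexes II and III with cytochrome c, -0.41 for complex IV, -0.31 for ATP synthase, -0.32 for the TCA cycle and -0.48 for fatty acid uptake and oxidation. It was -0.28 for PPAR targets, -0.24 for branched-chain amino acid catabolism, -0.29 for mitochondrial dynamics and import, -0.28 for the mitochondrial ribosome, -0.39 for ketone and lactate handling and -0.23 for endothelial markers. It was 0.13 for the cytosolic ribosome, 0.10 for fast-fibre genes, 0.15 for glycolysis and glycogen, 0.25 for myogenic regulators, 0.22 for fibroblast markers and 0.27 for clock genes. With an estimated correlation PPAR targets (adjusted p = 0.102), branched-chain amino acid catabolism (adjusted p = 0.0995), the cytosolic ribosome (adjusted p = 0.0754), glycolysis (adjusted p = 0.0608), endothelial markers (adjusted p = 0.368), fibroblast markers (adjusted p = 0.388) and lipogenesis (adjusted p = 0.398) lost their calls. For lipogenesis and LXR targets the median difference was -0.0074, the mean 0.25 and the test upward (adjusted p = 0.0444). That call was lost after quantile normalization (adjusted p = 0.0716), without CON 1 and NCoR1-MKO 5 (0.0672), without PGC-1alpha-mTg 2 and 3 (0.118) and in 10 of 20 fits that left out 1 array, at adjusted p up to 0.176.

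In 23 of 402 sets of 5 arrays, 5.72 percent, the highest or lowest array stood apart from the rest by a large share of the set's range, and chance gives about 5 percent. PGC-1alpha-mTg 5 was the highest of its group for Acadvl (gap over range 0.819), Casq2 (0.724) and Cds1 (0.807), and for the mean of fatty acid oxidation (0.711), mitochondrial dynamics (0.719) and smooth muscle markers (0.870). It had the lowest estimated array weight, 0.353. PGC-1alpha-mTg 2 was highest for Myod1 (0.814) and PGC-1alpha-mTg 1 for Neto2 (0.756). NCoR1-MKO 5 was lowest for Casr (0.770) and Ppargc1b (0.789) and highest for Musk (0.783), NCoR1-MKO 2 was lowest for Ndufb8 (0.762), and NCoR1-MKO 4 was highest for immediate early genes (0.816). CON 1 was highest for lipogenesis (0.801) and blood markers (0.833). WT 5 was highest for Car2 (0.733) and atrophy genes (0.720) and lowest for Prkag3 (0.841) and macrophage markers (0.832). WT 1 was highest for Mb (0.735), WT 2 lowest for Tfam (0.926) and highest for blood markers (0.765), and WT 4 lowest for the NCoR complex (0.799).

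Probe sets outside the comparisons also carried changes. Of the 1621 with several symbols, 41 were called in the knockout and 417 in the transgenic mice, and of the 12146 without a symbol here, 62 and 1258.

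Other splits of the same arrays were counted for each result of the fit, 100 splits each with the real one included. For the 525 knockout genes 1 split, the real one, gave as many, and the highest of the others was 8. The same held for the 5575 transgenic genes (1 split, highest other 2779), the 3022 genes of the difference (1 split, highest other 6) and the 12792 genes of WT against CON (1 split, highest other 4485). For the counts other than WT against CON, a chance division of these arrays is excluded only in that 1 of 100 lies under 5 percent. Chance among mice was not tested, since the arrays may not be separate mice. For WT against CON the splits decide nothing, since the cohorts appear to have been normalized separately. For the 329 shared genes, with the knockout cohort redrawn, 1 split gave as many and the highest other was 1, but this decides nothing, since the redrawn splits called at most 8 knockout genes. With the 525 genes of smallest p taken in every split, 1 split, the real one, gave as many as 329 in 1 direction, and the highest other was 271. Chance is excluded there only in that 1 of 100 lies under 5 percent, in a test chosen after the results were seen. The correlation of 0.32 was reached in size by 2 splits, and 1 other gave more, 0.34. Chance is excluded there only in that 2 of 100 lies under 5 percent. For the counts of lists chance cannot be excluded: 10 splits gave as many as the 15 of the knockout (median of the others 8, highest 17), 6 as many as the 22 of the transgenic mice (median 14, highest 23) and 12 as many as the 19 of the difference (median 11, highest 23).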

How the results depend on the processing

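The covariate fits and the fits without CON 1 and NCoR1-MKO 5, or without PGC-1alpha-mTg 2 and 3, were chosen after the data were seen. Over 288 single-gene results and all alternatives, 9370 of 9776 comparisons kept direction and side of the threshold, 387 lost the call, 17 gained one and 2 reversed. Of the 5760 that left out 1 array, 5548 kept both, 207 lost the call, 5 gained one and 0 reversed. The reversals came with the slow-fibre covariate: Fabp4 at -0.034 in the knockout and Tpm3 at 0.024 in the transgenic mice, at adjusted p = 0.959 and 0.872; the cause was not tested. Testing all probe sets called 20449 in WT against CON, since more were tested. A fold minimum of 1.2 left 308 knockout genes, 2991 transgenic genes, 8475 genes of WT against CON and 177 shared genes, by its construction. An estimated correlation left 5, 14 and 12 lists for the knockout, the transgenic mice and the difference, and fry called 13, 28 and 23. The slow-fibre covariate left 303 knockout genes and 188 shared genes, and over the 329 shared genes it widened the knockout standard errors by a median factor of 1.29. Leaving out 1 array, the counts ranged from 370 (without CON 3) to 617 (without PGC-1alpha-mTg 5) for the knockout, 4868 to 6544 for the transgenic mice, 2648 to 3736 for the difference, 12276 to 13098 for WT against CON and 219 (without CON 3) to 376 (without PGC-1alpha-mTg 5) for shared genes. The correlation ranged from 0.27 to 0.34, and the lists from 13 to 17, 20 to 24 and 18 to 21. Without CON 1 and NCoR1-MKO 5 the counts were 472, 5530, 2684, 12398 and 280, and without PGC-1alpha-mTg 2 and 3 they were 575, 4304, 2436, 13119 and 314. The replicate numbers were taken as names of samples, not as pairs. Residuals of same-numbered arrays correlated at -0.13 to 0.04 in the knockout cohort, where 0 of them correlated best with their own number. In the other cohort they correlated at -0.23 to 0.20, and 2 did so. So few correlations cannot exclude a pairing. With the replicate number as a block 370 knockout genes were called, 337 of them among the 525, and 5318 transgenic genes, 5117 of them among the 5575. With camera under the other scalings or without those pairs of arrays, lists of the difference that gained a call were antioxidant defence (adjusted p = 0.0497 after quantile normalization), angiogenic factors (0.0497 there, 0.0498 with medians centred, 0.0120 without PGC-1alpha-mTg 2 and 3), smooth muscle markers (0.0478 without those arrays) and macrophage markers (0.0152 without them, 0.00470 without CON 1 and NCoR1-MKO 5). Fibroblast markers lost their call in the last (0.0868). With 1 array left out angiogenic factors, antioxidant defence, macrophage markers and neuromuscular junction gained a call in some fits. With fry the difference gained antioxidant defence (0.000521), angiogenic factors (0.000564), neuromuscular junction (0.00386), mitochondrial gene regulators (0.00598) and NCoR complex and nuclear receptors (0.0309) and lost fibroblast markers (0.0632), and the knockout lost slow-fibre genes (0.0521) and lipogenesis (0.0550). The transgenic mice gained mitochondrial gene regulators (2.83e-06), insulin and growth signalling (3.90e-05), neuromuscular junction (7.30e-05), NCoR complex and nuclear receptors (0.000369), atrophy (0.00560) and nerve markers (0.0438). Signal over background was not given, so what the dim genes allow was read only from leaving out the dimmest 40 percent, with 660 knockout and 5453 transgenic genes called.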

Other observations

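The 13 families in this part were chosen after the data were seen, and so were the 3 genes set against a glucocorticoid-response score and the test of their shrinkage, with its rule that a covariate must move folds by 1 SE to count.

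Beyond the lists, several families passed the set test in PGC-1alpha-mTg, where 2371 of all 19938 genes were higher and 3204 lower. Mitochondrial solute carriers of the Slc25 family had 23 of 46 members higher and 4 lower (adjusted p = 3.16e-06; adjusted p = 0.0195 with an estimated correlation), with Slc25a34 at 1.16 ± 0.10. All 7 complex I assembly factors rose, at a median of 0.49 (adjusted p = 4.16e-07; adjusted p = 0.0195 with an estimated correlation), with Ndufaf1 at 0.89 ± 0.06 and Ndufaf6 at 0.88 ± 0.04. Aminoacyl-tRNA synthetases split by compartment. Of 16 mitochondrial ones 10 rose, Yars2 among them (0.80 ± 0.05), and of 16 cytosolic ones 8 fell, Tars among them (-0.42 ± 0.06). Their set tests passed (adjusted p = 1.29e-05 and 0.000454) but not with an estimated correlation (adjusted p = 0.0917 and 0.1995 with an estimated correlation). Proteasome subunits had 16 of 39 lower and 3 higher, with Psmd8 at -0.48 ± 0.05, and translation initiation factors 22 of 49 lower and 5 higher, with Eif4b at -0.44 ± 0.06 (adjusted p = 0.00116 and 0.000387; adjusted p = 0.1995 and 0.225 with an estimated correlation). The initiation factor family was taken by symbol and also holds the gene of an inhibitory binding protein, Eif4ebp2 (-0.45 ± 0.05). Histones had 13 of 44 lower, with H1f2 at -0.52 ± 0.05 (adjusted p = 0.00908; adjusted p = 0.1995 with an estimated correlation). Zinc finger genes of the Zfp series had 83 of 347 lower and 21 higher (adjusted p = 0.00126; adjusted p = 0.225 with an estimated correlation), and peroxins 4 of 14 higher (adjusted p = 0.0330; adjusted p = 0.253 with an estimated correlation). Olfactory receptors had 57 of 1027 higher and 1 lower, both smaller shares than over all genes, at a median of 0.05 (adjusted p = 0.00126, and 0.280 with an estimated correlation). The direction of each of these medians held under both other scalings. Potassium channel subunits (adjusted p = 0.0560), lysosomal proton pump subunits (adjusted p = 0.730) and collagens (adjusted p = 0.963) did not pass. In the knockout none of the 13 families passed, with adjusted p of the set test from 0.0560 upwards.

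Odf3l2, Lgi1 and Slc25a30, which fell in the knockout, were picked because they varied with glucocorticoid-response genes within groups, so no test of that relation is given. A stress state at sampling could have lowered them. The score of such genes differed between NCoR1-MKO and CON by -0.15 with an exact permutation p of 0.508, which did not decide. With the score as a covariate the falls were -1.30 ± 0.20 for Odf3l2, -1.44 ± 0.20 for Lgi1 and -1.19 ± 0.14 for Slc25a30, the lowest ratio to the fall without it being 0.876. Since this covariate moved no fold by 1 SE, that decides nothing either, and a stress state stays open for these genes.

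Sequence from another mouse strain around the targeted gene could change neighbouring genes. In the knockout 3 percent of the 100 nearest genes were called (Hs3st3a1, Srebf1 and Tvp23b), against 2.63 percent elsewhere (one-sided Fisher exact p = 0.492), which argues against such an effect on many neighbours.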
